A study of Arabidopsis thaliana with 17 samples.

How the data were processed

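Transcript levels had been measured on 17 ATH1 arrays, each hybridized with material from 5 µg of total RNA of 1 pool of 10 plants, for 7 genotypes with 2 or 3 arrays each. The values are signal intensities that the authors made with GCOS and the MAS5 algorithm per the labels, on a linear scale and scaled per array; versions of these programs are not given in the sources used here. In the deposited values the 2% trimmed mean was 100 in the 11 arrays of Col-0, stn7-1, psad1-1 and psad1-1 stn7-1 and 500 in the 6 arrays of Wassilewskija, psae1-3 and psae1-3 stn7-1. The analysis plan, fixed before the data were examined, had no further scaling; since the targets differ 5-fold, each array was brought to a 2% trimmed mean of 100, a change made after the data were seen. After it the array medians were 33.5 to 39.1 in the first set and 29.3 to 33.5 in the second.

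Signals below the 10th percentile (1.57) were set to it, log2 values were taken, 64 control probe sets were left out, and the 40% of probe sets with the lowest mean were dropped, which left 13648. A linear model with 1 mean per genotype was fitted over all 17 arrays with limma 3.58.1 in R 4.3.3, with moderated variances and a trend on the mean (10 residual and 6.04 prior degrees of freedom). A probe set passed a comparison at a Benjamini-Hochberg adjusted p of 0.05. Against both wild types a probe set counted when it passed against each in the same direction. The difference of STN7 effects was tested as an interaction in each mutant background. All tests were two-sided. SE is that of the log2 change in the moderated fit, and SD that of the scaled signals between arrays of a genotype. A background signal of 8.15 was taken after the data were seen as the 95th percentile of 315 values of control probe sets without a target. A signal below it is no sign of expression, and folds written with "at least" set each array signal under it to it before the group means are taken.

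Gene names came from an annotation table that lists 14016 of the 22810 probe sets, 13513 of them with 1 gene and 503 with several; 8730 further probe sets were tested and counted where they were bright enough, but carry no name. Among the tested probe sets 7354 had 1 gene (7286 genes). The order along chromosomes follows the chromosome and start position listed for each gene. Genes named in the text followed a rule fixed in advance. It took the mutated genes, the 8 highest and 8 lowest changes per mutant that passed against both wild types with all arrays beyond those of the 5 wild-type arrays, the 5 highest and 5 lowest without overlap in the other comparisons, and up to 4 passing members per list. From these the text names those that carry a comparison, and a few list members were added after their values were seen (PSBW, PSBY, and those named again to follow a gene across comparisons).

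Gene lists written from background knowledge before the data were examined were tested with camera (limma) at its preset correlation of 0.01 between members, with Benjamini-Hochberg adjustment over the 8 lists with at least 3 tested members. Another 10 lists written after the data were seen were adjusted as a separate family, where the plan had 1 family. The tests were repeated with an estimated correlation, under which no list passed in any comparison, and with fry, which tests whether members move one way on balance and compares with no other set. Lists with 1 or 2 tested members were not tested as sets: photosystem I subunits, photosystem II subunits, jasmonate (PDF1.2), circadian clock (GI), sugar and starvation (APL3), mitochondrial stress (NDB2 and AT2G21640) and senescence (WRKY53). Light-harvesting complex I, heat shock proteins, salicylic acid defence, iron deficiency and the markers of epidermis and guard cells, phloem and inflorescence had 0 tested members and give no result. The 8 fixed lists tested cover only part of their genes. Tested members were 4 of 16 for tetrapyrrole synthesis, 4 of 24 for plastid ribosomal proteins, 5 of 22 for antioxidants and 4 of 13 for flavonoids and anthocyanins. They were 3 of 14 for light-harvesting complex II, 4 of 20 for electron carriers, 3 of 17 for the Calvin cycle and 4 of 14 for abscisic acid, cold and drought. Of 154 cytosolic ribosomal protein genes 90 were tested, and of 26 dark-induced genes 6.

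The processing was tested on simulated data with the group sizes of the study. With stn7-1 and Col-0 sizes (3 arrays each) 23, 42, 50 and 50 of 50 probe sets changed 1.5-fold, 2-fold, 4-fold and 8-fold were recovered and 8 unchanged ones called. With psae1-3 and Wassilewskija sizes (2 each) 12, 37, 50 and 49 were recovered and 11 unchanged ones called. The list test found the raised list and no unchanged one. Probe sets were simulated as independent, so this could not show how the list test fares when members are correlated. The alternatives tried were scaling to the array median, quantile normalization, other floors and filters, other model settings, and leaving out each array. Residual correlations gave no sign that replicate letters pair arrays across genotypes. Those of the 45 pairs with the same letter ran from −0.22 to 0.27 (median −0.04). Those of the 78 pairs with different letters ran from −0.37 to 0.34 (median 0.01). By a strict count, 0 of 17 arrays correlated best with their own letter in every other genotype. The C arrays could not enter that count, because some genotypes have no C.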

Results

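Transcript levels were measured with ATH1 arrays in Arabidopsis thaliana plants of 7 genotypes, in rosette leaves taken at an age of 4 weeks. STN7 is the thylakoid kinase that phosphorylates light-harvesting complex II in state transitions and is needed for the long-term response (LTR) to light quality, and PSAD and PSAE are the stromal subunits of photosystem I at which ferredoxin docks. The genotypes were the wild types Col-0 (3 arrays) and Wassilewskija (2), the single mutants stn7-1 (3), psad1-1 (2) and psae1-3 (2), and the double mutants psad1-1 stn7-1 (3) and psae1-3 stn7-1 (2). Each array held RNA from 1 pool of 10 plants, and the small number of arrays per genotype limits the precision.

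The 17 arrays fell into 2 sets by the scale of their deposited signals. Col-0, stn7-1, psad1-1 and psad1-1 stn7-1 made up the first set (11 arrays, trimmed mean 100), and Wassilewskija, psae1-3 and psae1-3 stn7-1 the second (6 arrays, trimmed mean 500). The 25S rRNA control read 522 to 2128 in the first set and 15.1 to 22.1 in the second, and the dap spike-in 0.322 to 3.25 and 129 to 217. Arrays of the same genotype correlated at 0.962 to 0.983 (13 pairs), arrays of other genotypes in the same set at 0.859 to 0.982 (57 pairs), and arrays of different sets at 0.770 to 0.897 (66 pairs). No genotype was present in both sets, so accession and array set cannot be told apart, and the labels do not say which wild type was the parent of which mutant. Each mutant is therefore described against the wild type of its own set, a choice made after the data were seen, and the planned count against both wild types is given beside it.

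PSAE-1 (AT4G28750), the gene mutated in psae1-3, lost nearly all of its signal in both lines that carry the mutation. Its mean signal was 5009 ± 136 (SD, n = 2) in Wassilewskija, 43.5 ± 27.9 (n = 2) in psae1-3 and 7.81 ± 3.62 (n = 2) in psae1-3 stn7-1. Against Wassilewskija it changed by −7.02 log2 in psae1-3 (SE 0.34, adjusted p = 3.12e-09) and by −9.41 log2 in psae1-3 stn7-1 (SE 0.34, adjusted p = 2.13e-11). The latter is at least 545-fold, because replicate A of psae1-3 stn7-1 read 5.25, under the background of 8.15, and replicate B 10.4. PSAE-1 did not pass the test in stn7-1 (−0.03 log2, adjusted p = 0.952), psad1-1 (−0.24 log2, adjusted p = 0.573) or psad1-1 stn7-1 (−0.15 log2, adjusted p = 0.702) against Col-0. STN7, PSAD1, PSAD2 and PSAE2 had no probe set in the gene table used here, so the other mutations were not checked by their own transcripts.

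**Figure D1:**
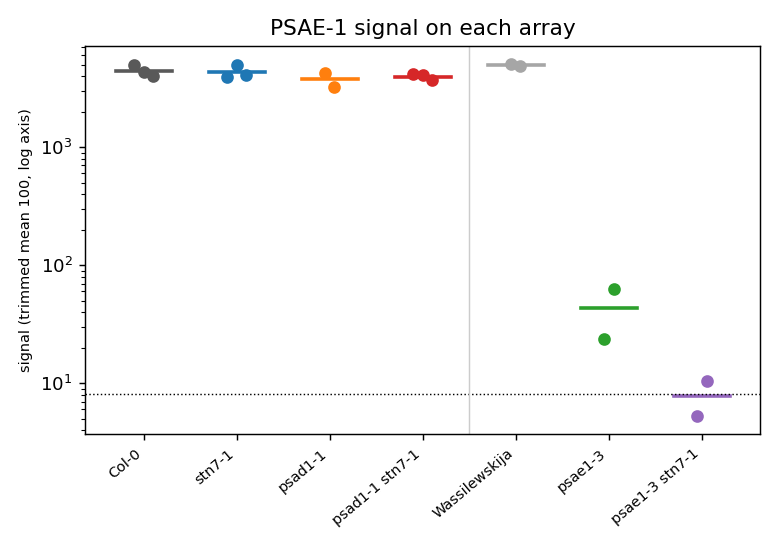
Signal of PSAE-1 (log scale, arrays scaled to a trimmed mean of 100) in the 7 genotypes, with 1 point per array, a horizontal bar at each group mean, a dotted line at the background signal of 8.15 and a grey line between the array sets. PSAE-1 was 5009 in Wassilewskija, 43.5 in psae1-3 and 7.81 in psae1-3 stn7-1.

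In stn7-1, genes of the last steps of anthocyanin synthesis were among those that fell most. AT4G14090, which encodes an anthocyanin glucosyltransferase, fell from 170 ± 27.7 in Col-0 to 17.7 ± 4.09 in stn7-1 (SD, n = 3 each), a change of −3.28 log2 (SE 0.64, adjusted p = 0.00294). DFR (AT5G42800), which encodes dihydroflavonol reductase, changed by −2.80 log2 (SE 0.67, adjusted p = 0.00933). UF3GT (AT5G54060), a second anthocyanin glycosyltransferase gene, changed by −2.59 log2 (SE 0.42, adjusted p = 0.00093), and the flavonoid glucosyltransferase UGT78D2 (AT5G17050) by −0.62 log2 (adjusted p = 0.00933). AT1G80130 fell from 349 ± 63.5 to 83.5 ± 3.28 (−2.05 log2, SE 0.22, adjusted p = 0.000165), and APL3 (AT4G39210), a large subunit of ADP-glucose pyrophosphorylase, changed by −0.97 log2 (SE 0.21, adjusted p = 0.00554). The sugar transporter genes SWEET2 (AT3G14770) and SWEET13 (AT5G50800) moved in opposite directions, by 1.03 log2 (SE 0.11, adjusted p = 0.000165) and −1.10 log2 (SE 0.29, adjusted p = 0.016, and 0.0664 without stn7-1 replicate C). The senescence-related transcription factor gene WRKY53 (AT4G23810) changed by −1.46 log2 (adjusted p = 0.0212), but did not pass without Col-0 replicate B (adjusted p = 0.116), stn7-1 replicate A (0.0897) or stn7-1 replicate C (0.0574).

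Plastid ribosomal protein genes and tetrapyrrole genes were among those that rose in stn7-1 by smaller amounts. The plastid ribosomal protein genes AT3G13120 and AT4G01310 rose by 0.81 and 0.68 log2, and the tetrapyrrole genes GSA1 (AT5G63570) and PORB (AT4G27440) by 0.68 (SE 0.15, adjusted p = 0.00514) and 0.81 log2 (adjusted p = 0.00281). NTRC (AT2G41680), the plastid thioredoxin reductase, rose by 0.90 log2 (adjusted p = 0.00102), and the chloroplast ascorbate peroxidase genes SAPX (AT4G08390) and TAPX (AT1G77490) by 0.68 (adjusted p = 0.0115) and 0.43 log2. THI2.2 (AT5G36910), a thionin gene, rose from 223 ± 36.3 to 487 ± 72.6 (1.13 log2, SE 0.37, adjusted p = 0.0422), and the glutaredoxin-family gene AT3G62950 by 2.13 log2 (SE 0.64, adjusted p = 0.0286, at least 2.53-fold with signals under the background of 8.15 set to it). THI2.2 did not pass when any 1 of the 6 Col-0 and stn7-1 arrays was left out (adjusted p = 0.0520 without Col-0 replicate A to 0.141 without Col-0 replicate B). AT3G62950 had adjusted p = 0.135 without Col-0 replicate B, 0.0933 without stn7-1 replicate A and 0.108 without stn7-1 replicate B. Of the photosystem I subunits PSAN (AT5G64040) stood at −0.10 log2 (adjusted p = 0.386), of the photosystem II subunits PSBW at −0.13 log2 (adjusted p = 0.454) and PSBY at −0.01 log2 (adjusted p = 0.941), and the clock gene GI (AT1G22770) stood at 0.34 log2 (adjusted p = 0.606).

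Between stn7-1 and Col-0, 2580 of 13648 probe sets passed, 1329 higher and 1251 lower, with 108 and 220 of them at least 2-fold. Under scaling to the array median 71.8% of the calls were higher, where the scaling used here gave 51.5%. The count was 1326 without Col-0 replicate B and 1451 without stn7-1 replicate B. Against both wild types 1354 probe sets passed in the same direction (728 higher, 626 lower, but 786 and 406 under scaling to the array median), and the count was 778 and 728 without the same 2 arrays.

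By the list test, which is camera at its preset correlation unless another is named, 4 of the 8 fixed lists with at least 3 tested members passed between stn7-1 and Col-0. Counts are out of the tested members only, and most genes of each fixed list had no named probe set here. Tetrapyrrole synthesis rose (3 of 4 members higher, 0 lower, 1 not past the test, median 0.53 log2, adjusted p = 0.00196), as did plastid ribosomal proteins (4 of 4 higher, median 0.57 log2, adjusted p = 0.000358) and antioxidants (4 of 5 higher, 1 not past the test, median 0.47 log2, adjusted p = 0.00554). Flavonoids and anthocyanins fell (4 of 4 lower, median −2.70 log2, adjusted p = 0.000616). Adjusted over the list alone, 3, 4, 5 (4 higher, 1 lower) and 4 members passed. Each of the 4 lists had adjusted p = 0.129 with an estimated correlation between members. Against Wassilewskija none of the 4 passed (adjusted p = 0.681 for tetrapyrrole synthesis and 0.267 for each of the others). The planned rule of a call against both wild types therefore called none of them in stn7-1. Light-harvesting complex II (0 of 3, adjusted p = 0.968), electron carriers (0 of 4), the Calvin cycle (0 of 3, adjusted p = 0.365) and abscisic acid, cold and drought genes (0 of 4, adjusted p = 0.968) did not pass. Among the lists added after the data were seen, cytosolic ribosomal proteins rose (64 of 90 members higher, 0 lower, median 0.66 log2, adjusted p = 3.23e-27, and 0.299 with an estimated correlation), led by AT2G44120 at 1.17 log2. The list of plastid-encoded gene expression machinery passed as higher (5 of 19 higher, median 0.52 log2, adjusted p = 0.00114), and the list test pointed up for plastid-encoded photosynthesis genes (0 of 33 past the test singly, median 0.40 log2, adjusted p = 0.00142). These lists had adjusted p = 0.535 and 0.624 with an estimated correlation, and 0.0863 and 0.247 without Col-0 replicate B. Against Wassilewskija the list test pointed down for both (adjusted p = 0.000227 and 1.39e-05). Of the remaining added lists, glutathione S-transferases (2 of 7 lower, adjusted p = 0.11), calmodulin-like proteins (2 of 5 lower, adjusted p = 0.11) and expansins (2 higher and 1 lower of 11, adjusted p = 0.744) did not pass. SWEET sugar transporters (1 higher and 1 lower of 7), mitochondrial-encoded genes (1 lower of 7) and dark-induced genes (0 of 6, adjusted p = 0.71) did not pass either. With fry, glutathione S-transferases and calmodulin-like proteins passed (lower, adjusted p = 0.0205 and 0.0196), and the 2 plastid-encoded lists did not (0.134 and 0.279).

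**Figure D2:**
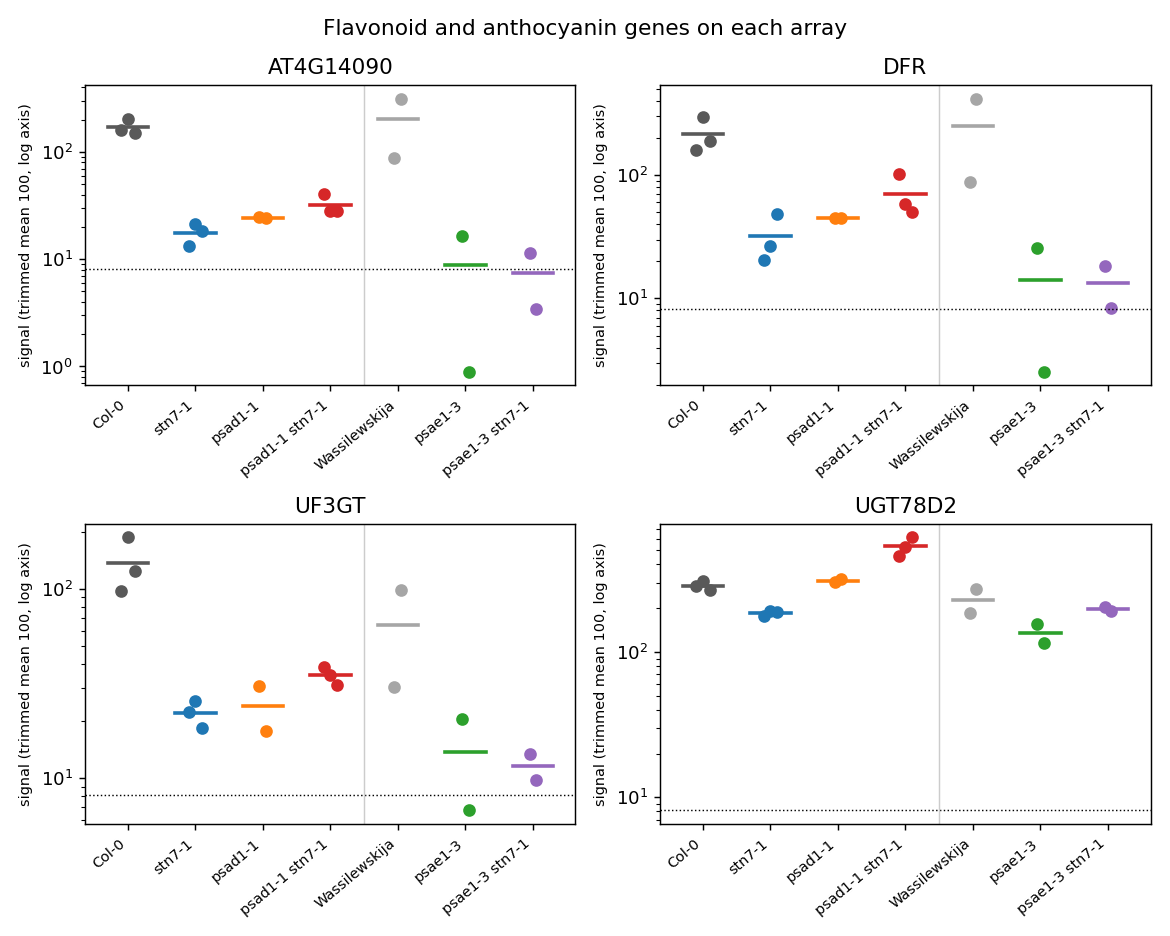
Signal of AT4G14090, DFR, UF3GT and UGT78D2 (log scale, arrays scaled to a trimmed mean of 100) in the 7 genotypes, with 1 point per array, a horizontal bar at each group mean, a dotted line at the background signal of 8.15 and a grey line between the array sets. AT4G14090 was 170 in Col-0, 17.7 in stn7-1 and 32.3 in psad1-1 stn7-1, and UGT78D2 was 286, 186 and 532.

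In psad1-1, SWEET2, APL3 and COR15A (AT2G42540) were among the most changed genes. SWEET2 rose from 100 ± 4.07 in Col-0 (SD, n = 3) to 1021 ± 103 in psad1-1 (n = 2), a change of 3.35 log2 (SE 0.13, adjusted p = 5.13e-11), and SWEET13 changed by −2.76 log2 (SE 0.33). APL3 fell from 221 ± 20.3 to 21.5 ± 6.65 (−3.39 log2, SE 0.24, adjusted p = 3.49e-08), and the cold-regulated COR15A from 1144 ± 171 to 118 ± 12.4 (−3.27 log2, SE 0.29, adjusted p = 4.41e-07). CYP71B26 (AT3G26290), a cytochrome P450 gene, fell from 392 ± 22.9 to 14.2 ± 0.258 (−4.79 log2, SE 0.15, adjusted p = 5.2e-12). AT3G14200 changed by −6.01 log2 (SE 0.43), which is at least 16.2-fold when its signal in psad1-1 is set to the background of 8.15, and AT2G40435 by −4.38 log2 (at least 17.3-fold). The clock gene GI changed by −3.74 log2 (SE 0.45, adjusted p = 8.16e-06, at least 6.87-fold from a Col-0 signal of 56.1 ± 3.9).

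AT3G62950 rose from 8.09 ± 6.03 in Col-0 to 129 ± 13.1 in psad1-1 (4.45 log2, SE 0.72, adjusted p = 0.000133, at least 12.7-fold), the glycine-rich protein gene AT2G05540 by 3.87 log2 (SE 0.32, adjusted p = 2.16e-07) and PYK10 (AT3G09260), the beta-glucosidase of endoplasmic reticulum bodies, from 25.3 ± 10.2 to 283 ± 107 (3.50 log2, SE 0.54, adjusted p = 9.79e-05). NTRC rose by 1.09 log2 (SE 0.16, adjusted p = 6.72e-05), while PORB, which rose in stn7-1, changed by −0.64 log2 in psad1-1 (SE 0.18, adjusted p = 0.00836). AT4G14090 fell to 24.4 ± 0.3 (−2.79 log2, SE 0.72, adjusted p = 0.00545) and DFR changed by −2.21 log2 (SE 0.75, adjusted p = 0.0273). DFR did not pass without Col-0 replicate B (adjusted p = 0.0759), psad1-1 replicate A (0.101) or psad1-1 replicate B (0.111). The photosystem I gene PSAN changed by −0.34 log2 (adjusted p = 0.00509) but had adjusted p = 0.131 under scaling to the array median and 0.0958 without psad1-1 replicate B.

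Between psad1-1 and Col-0, 5521 probe sets passed, 2640 higher and 2881 lower, with 671 and 1090 at least 2-fold. Under scaling to the array median 63.6% of the calls were higher against 47.8% here, and the median of all probe sets moved to 0.119 log2. Leaving out psad1-1 replicate B gave the lowest count of 3868. Against both wild types 3439 probe sets passed (1609 higher, 1830 lower, but 1813 and 1433 under scaling to the array median and 1778 and 1666 under quantile normalization).

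Abscisic acid, cold and drought genes were the only fixed list that passed between psad1-1 and Col-0 (4 of 4 lower, median −1.60 log2, adjusted p = 0.0215, and 0.526 with an estimated correlation), with COR15B (AT2G42530) at −1.91 and COR47 (AT1G20440) at −1.30 log2 beside COR15A. Flavonoids and anthocyanins did not pass as a list (3 of 4 lower, 1 not past the test, median −2.35 log2, adjusted p = 0.195). The same held for plastid ribosomal proteins (3 of 4 higher, median 0.52 log2, adjusted p = 0.0637, and 0.0295 without psad1-1 replicate B), antioxidants (4 of 5 higher, 1 lower, adjusted p = 0.18) and tetrapyrrole synthesis (2 of 4 higher, 1 lower, adjusted p = 0.366). Cytosolic ribosomal proteins rose (52 of 90 higher, 1 lower, median 0.59 log2, adjusted p = 3.42e-09, and 0.716 with an estimated correlation). Glutathione S-transferases did not pass as a list (5 of 7 lower, median −0.72 log2, adjusted p = 0.0994), although GSTU20 (AT1G78370) changed by −1.28 log2. Expansins (1 higher and 5 lower of 11, adjusted p = 0.174) and calmodulin-like proteins (1 higher and 3 lower of 5, adjusted p = 0.258) did not pass either. SWEET sugar transporters (2 higher and 2 lower of 7) had a median of −0.20 log2 while the list test pointed up with adjusted p = 0.99. With fry, plastid ribosomal proteins (adjusted p = 0.00666), antioxidants (0.00716), tetrapyrrole synthesis (0.0432), SWEET sugar transporters (0.00427) and dark-induced genes (0.036) passed as higher. Light-harvesting complex II (0.00716), flavonoids and anthocyanins (0.0432), glutathione S-transferases (0.000235), calmodulin-like proteins (0.00214) and expansins (0.00427) passed as lower.

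In psae1-3, anthocyanin genes were again among those that fell most. AT4G14090 fell from 201 ± 160 in Wassilewskija to 8.75 ± 11.1 in psae1-3 (SD, n = 2 each), a change of −5.02 log2 (SE 0.79, adjusted p = 0.00123), and DFR from 252 ± 233 to 14.2 ± 16.4 (−4.56 log2, SE 0.82, adjusted p = 0.00277). In psae1-3 replicate B both lay under the background, at 0.897 and 2.56, so the sizes of these falls are not fixed (at least 14.3-fold and 13.2-fold). UF3GT, which read 6.77 in psae1-3 replicate B, changed by −2.21 log2 (SE 0.51, adjusted p = 0.0108, at least 4.22-fold) and UGT78D2 by −0.74 log2 (SE 0.18, adjusted p = 0.0146). UF3GT did not pass without Wassilewskija replicate B (adjusted p = 0.154) or psae1-3 replicate B (0.124), nor UGT78D2 without the same arrays (0.186 and 0.146). AT3G62950 rose by 4.48 log2 (SE 0.78, adjusted p = 0.00249, at least 5.00-fold), and AT1G13650 from 167 ± 8.28 to 611 ± 39 (1.87 log2, SE 0.21, adjusted p = 0.000118). TAPX rose by 0.69 log2 (SE 0.12, adjusted p = 0.00261), and the plastid ribosomal protein genes AT3G13120 and AT4G01310 by 0.70 log2 each (adjusted p = 0.0520 and 0.0914 without Wassilewskija replicate B). NdhN (AT5G58260), a nuclear-encoded subunit of the chloroplast NADH dehydrogenase-like (NDH) complex, rose by 0.60 log2, and GI did not pass (0.06 log2).

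Between psae1-3 and Wassilewskija, 1681 probe sets passed, 739 higher and 942 lower, with 106 and 260 at least 2-fold. The median of all probe sets was −0.11 log2, and 77.5% of the calls were higher under scaling to the array median and 55.4% under quantile normalization, where the scaling used here gave 44.0%. The count was 548 without Wassilewskija replicate B, 1032 without psae1-3 replicate A and 887 without psae1-3 replicate B. Against both wild types 1196 probe sets passed (547 higher, 649 lower, but 1142 and 261 under scaling to the array median and 454 and 347 under quantile normalization), and the count was 414 and 612 without Wassilewskija replicate B and psae1-3 replicate B.

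Plastid ribosomal proteins rose between psae1-3 and Wassilewskija (4 of 4 higher, median 0.64 log2, adjusted p = 0.000133). The list test also pointed up for tetrapyrrole synthesis (1 of 4 higher and 3 not past the test, median 0.41 log2, adjusted p = 0.00766) and antioxidants (1 of 5 higher, 4 not past the test, median 0.49 log2, adjusted p = 0.0127). The list of flavonoids and anthocyanins fell (4 of 4 lower, median −3.38 log2, adjusted p = 0.000333). Adjusted over the list alone, 4, 2, 5 (4 higher, 1 lower) and 4 members passed, and each list had adjusted p = 0.150 with an estimated correlation. By itself tetrapyrrole synthesis had adjusted p = 0.152 and the list of antioxidants and oxidative stress markers 0.125 under quantile normalization, and the latter 0.166 without Wassilewskija replicate B. Electron carriers (2 of 4 higher, adjusted p = 0.0696) did not pass but did with fry (0.00851). The list test pointed up for cytosolic ribosomal proteins (7 of 90 higher, 0 lower, median 0.45 log2, adjusted p = 6.51e-17, and 0.533 with an estimated correlation). The plastid-encoded photosynthesis genes, plastid-encoded NDH complex and plastid-encoded gene expression machinery passed as lists (higher, adjusted p = 0.014, 0.0148 and 0.00511), with 0 of 33, 1 of 9 and 0 of 19 members past the test singly. These values became 0.754, 0.533 and 0.533 with an estimated correlation and 0.257, 0.188 and 0.188 without psae1-3 replicate B, and the first and second were 0.101 and 0.0727 without Wassilewskija replicate A. With fry they were 0.706, 0.328 and 0.431, and cytosolic ribosomal proteins had 0.243. By the planned rule of a call against both wild types, cytosolic ribosomal proteins were called in stn7-1, psad1-1 and psad1-1 stn7-1, and flavonoids and anthocyanins in psae1-3 and psae1-3 stn7-1. The same rule called tetrapyrrole synthesis, plastid ribosomal proteins and the 3 plastid-encoded lists in psae1-3. It called no other list in any mutant.

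**Figure D3:**
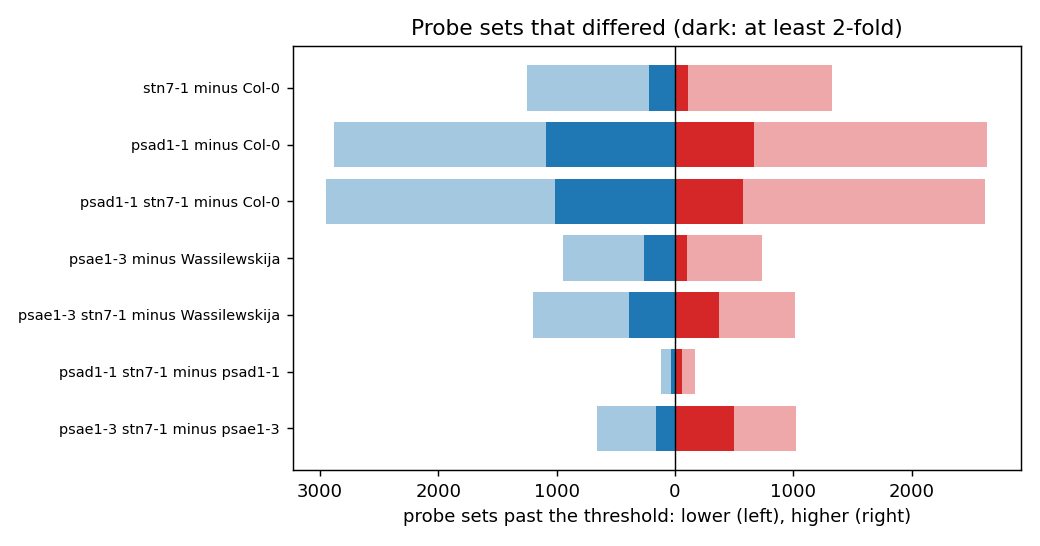
Number of probe sets past the test in each comparison, lower to the left and higher to the right, with changes of at least 2-fold in dark colours, out of 13648 tested. Among the comparisons of mutants within an array set the largest count was 5572 in psad1-1 stn7-1 against Col-0 and the smallest 285 in psad1-1 stn7-1 against psad1-1.

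In psad1-1 stn7-1, AT2G05540 rose from 42.4 ± 8.93 in Col-0 to 1368 ± 280 in the double mutant (SD, n = 3 each), a change of 5.01 log2 (SE 0.29, adjusted p = 3.36e-09), PYK10 by 4.34 log2, AT3G62950 by 3.77 log2 (at least 7.90-fold) and SWEET2 by 3.04 log2. AT2G25625 changed by −4.87 log2 (at least 10.8-fold), APL3 by −3.32 log2, COR15A by −3.22 log2 and PORB by −1.22 log2 (SE 0.16, adjusted p = 1.42e-05). GI changed by −1.67 log2 (SE 0.40, adjusted p = 0.0032). AT4G14090 fell to 32.3 ± 6.82 (−2.41 log2, adjusted p = 0.00655), while UGT78D2 rose from 286 ± 21.4 to 532 ± 77.7 (0.89 log2, SE 0.15, adjusted p = 0.000174).

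Against Col-0, 5572 probe sets passed in psad1-1 stn7-1 (2623 higher, 2949 lower, with 579 and 1012 at least 2-fold), and 58.1% of the calls were higher under scaling to the array median where the scaling used here gave 47.1%. Against both wild types 3762 passed (1779 higher, 1983 lower, but 1803 and 1711 under scaling to the array median and 2070 and 1888 under quantile normalization). Plastid ribosomal proteins rose (4 of 4 higher, median 0.60 log2, adjusted p = 0.0172) and abscisic acid, cold and drought genes fell (3 of 4 lower, 1 not past the test, median −1.45 log2, adjusted p = 0.0254), each with adjusted p = 0.375 with an estimated correlation. Flavonoids and anthocyanins (1 higher and 2 lower of 4, median −1.78 log2, adjusted p = 0.584) and antioxidants (4 higher and 1 lower of 5, adjusted p = 0.14) did not pass. With fry, antioxidants (adjusted p = 0.00341), SWEET sugar transporters (0.00119) and dark-induced genes (0.00985) passed as higher. Light-harvesting complex II (0.000694), glutathione S-transferases (0.00119), calmodulin-like proteins and expansins (0.0061 each) passed as lower. Members were split in some of these lists. SWEET sugar transporters had 2 higher and 2 lower of 7 (median 0.03 log2), calmodulin-like proteins 1 higher and 2 lower of 5, and expansins 1 higher and 6 lower of 11. Against Wassilewskija the list test pointed up for calmodulin-like proteins (adjusted p = 0.044). Cytosolic ribosomal proteins rose (83 of 90 higher, 1 lower, median 0.85 log2, adjusted p = 2.41e-20, and 0.595 with an estimated correlation), led by AT4G39200 at 1.55 log2.

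In psae1-3 stn7-1, several genes near or below background in Wassilewskija became strongly expressed. THI2.2 rose from 11.2 ± 10.5 in Wassilewskija to 555 ± 1.37 in psae1-3 stn7-1 (SD, n = 2 each), a change of 6.06 log2 (SE 0.45). AT1G76960 rose by 9.37 log2 (at least 134-fold), the TIR-NBS-LRR gene AT5G36930 by 5.58 log2 (at least 10.4-fold), AT1G51270 by 5.93 log2 (at least 11.8-fold, but 1.45 log2 in another probe set of the gene) and the chitinase-type gene CHI (AT2G43570) by 4.38 log2. THI2.2 and AT1G76960 read far above the background in Col-0 as well, so their rises go toward the Col-0 level and are not assigned to the loss of STN7. AT3G62950 rose by 3.85 log2 (at least 3.23-fold). AT5G15360 changed by −5.20 log2 (at least 14.7-fold), AT4G14090 by −4.73 log2 (SE 0.79, adjusted p = 0.000644, at least 17.2-fold), DFR by −3.95 log2 and UF3GT by −2.25 log2 (adjusted p = 0.00611). Without Wassilewskija replicate B the adjusted p of DFR was 0.0664 and that of UF3GT 0.111, and UF3GT had 0.0537 without double mutant replicate B.

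Against Wassilewskija, 2214 probe sets passed in psae1-3 stn7-1 (1014 higher, 1200 lower, with 373 and 390 at least 2-fold), where scaling to the array median gave 1123 higher and 905 lower. The count was 1288 without Wassilewskija replicate B, 1274 without replicate A of the double mutant and 1464 without its replicate B. Against both wild types 1169 passed (483 higher, 686 lower, but 687 and 428 under scaling to the array median), and the count was 723 and 659 without Wassilewskija replicate B and double mutant replicate A. The list of flavonoids and anthocyanins fell (3 of 4 lower, 1 not past the test, median −3.10 log2, adjusted p = 0.019). Its adjusted p was 0.393 with an estimated correlation, 0.239 without Wassilewskija replicate B and 0.0844 without double mutant replicate B. The antioxidants and oxidative stress markers did not pass (2 of 5 higher, adjusted p = 0.054, 0.00587 without Wassilewskija replicate A, and 0.0269 with fry, as for electron carriers). The list test pointed up for cytosolic ribosomal proteins, most of which did not pass singly (4 of 90 higher, median 0.21 log2, adjusted p = 0.000367, 0.895 with an estimated correlation, 0.589 with fry, and 0.644 without double mutant replicate B), and down against Col-0 (adjusted p = 0.0214).

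Between psad1-1 stn7-1 and psad1-1 few probe sets passed. AT3G52740 and AT3G44450 encode BIC1 and BIC2, inhibitors of cryptochromes. AT3G52740 rose from 33.7 ± 3.39 in psad1-1 (SD, n = 2) to 184 ± 59.9 in psad1-1 stn7-1 (n = 3), a change of 2.39 log2 (SE 0.22, adjusted p = 5.67e-05). AT3G44450 rose from 126 ± 29.4 to 580 ± 188 (2.17 log2, SE 0.23, adjusted p = 0.000212). AT3G56260 rose by 2.93 log2 (SE 0.35, adjusted p = 0.000828, at least 4.93-fold) and AT3G14200, which fell in psad1-1, by 2.90 log2 (adjusted p = 0.00349, at least 1.88-fold, and adjusted p = 0.129 without psad1-1 replicate B). GI rose by 2.07 log2 (SE 0.45, adjusted p = 0.0291, at least 2.16-fold) but did not pass without psad1-1 replicate A (adjusted p = 0.173) or replicates B (0.110) and C (0.113) of the double mutant. The ERF gene AT5G61590 changed by −1.91 log2 (adjusted p = 0.0201) and AT2G20670 by −1.88 log2 (adjusted p = 0.0321), with adjusted p of 0.255 and 0.383 without psad1-1 replicate B, 0.0669 and 0.112 without double mutant replicate B, and 0.0604 and 0.111 without its replicate C. UGT78D2 rose by 0.77 log2 (adjusted p = 0.0289), but had adjusted p of 0.0839 and 0.247 without psad1-1 replicates A and B, and 0.0866 and 0.113 without double mutant replicates B and C.

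In this comparison 285 probe sets passed, 168 higher and 117 lower (56 and 31 at least 2-fold). The count was 19 without psad1-1 replicate B, 35 without double mutant replicate B and 36 without its replicate C. Under scaling to the array median 43.4% of the calls were higher, where the scaling used here gave 58.9%. No fixed list passed, with flavonoids and anthocyanins at adjusted p = 0.218 (1 of 4 higher). Cytosolic ribosomal proteins had a median of 0.26 log2 and adjusted p = 1.28e-10 with 0 of 90 members past the test, and adjusted p = 0.806 with an estimated correlation and 0.6 with fry.

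Between the 2 psae1-3 lines, several genes rose from low signals to levels nearer those of Col-0 than of Wassilewskija. The thionin gene AT1G66100 rose by 8.80 log2 (SE 0.21, adjusted p = 1.35e-13, at least 210-fold) to 1709 ± 18.7 in psae1-3 stn7-1 (SD, n = 2), and ECS1 (AT1G31580), which encodes a cell wall protein, from 28.1 ± 18.7 in psae1-3 (n = 2) to 6522 ± 32.1 (8.04 log2, SE 0.30, adjusted p = 3.29e-11). AT1G76960 rose by 9.44 log2 (SE 0.52, adjusted p = 4.08e-09, at least 134-fold). CHI rose by 7.45 log2 (at least 42.5-fold), and past its Col-0 level. With signals under the background set to it, CHI in psae1-3 stn7-1 stood 4.38 log2 above Wassilewskija, which was only 0.86 log2 under Col-0. AT1G66100 read 2087 in Col-0 and 4.05 in Wassilewskija, ECS1 4938 and 44.7, and AT1G76960 249 and 1.65, so these rises are not assigned to the loss of STN7. CML41 (AT3G50770), a calmodulin-like gene, rose by 3.52 log2 (SE 0.50, adjusted p = 0.00017, at least 7.32-fold), the zinc finger gene STZ (ZAT10) by 2.73 log2 (SE 0.49, adjusted p = 0.00138) and the mitochondrial NAD(P)H dehydrogenase gene NDB2 (AT4G05020) by 1.19 log2 (SE 0.18, adjusted p = 0.000221). CML41 (120 in Col-0 and 13.7 in Wassilewskija) and STZ (1717 and 48.2) also moved toward the Col-0 level. AT5G15360 changed by −5.13 log2 (at least 14.0-fold), the ATP-citrate lyase gene ACLA-2 (AT1G60810) by −2.63 log2 (SE 0.14), and PSAE-1 itself by −2.39 log2 (SE 0.34, adjusted p = 0.00014, at least 4.21-fold). PORB changed by −0.87 log2 (adjusted p = 0.0063, but 0.0706 without psae1-3 replicate A and 0.0954 without double mutant replicate A).

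Between psae1-3 stn7-1 and psae1-3, 1677 probe sets passed, 1021 higher and 656 lower (502 and 163 at least 2-fold). The count was 969 without psae1-3 replicate A and 769 without double mutant replicate A. Under scaling to the array median 41.6% of the calls were higher where the scaling used here gave 60.9%, with the median of all probe sets at −0.10 log2. The plastid ribosomal proteins fell (3 of 4 lower, 1 not past the test, 4 adjusted over the list alone, median −0.48 log2, adjusted p = 0.00684). Their adjusted p was 0.723 with an estimated correlation, 0.0804 without double mutant replicate A and 0.0844 under quantile normalization. The calmodulin-like proteins rose as a list (3 of 5 higher, median 1.53 log2, adjusted p = 0.0143), toward Col-0 as well (Wassilewskija against Col-0 had a median of −3.05 log2). Their adjusted p was 0.162 with an estimated correlation, 0.082 without psae1-3 replicate B and 0.0937 without double mutant replicate A. The list test pointed down for the plastid-encoded gene expression machinery (0 of 19 past the test singly, median −0.33 log2, adjusted p = 0.0143) and for cytosolic ribosomal proteins (1 higher and 1 lower of 90, median −0.20 log2, adjusted p = 0.000884). Each had adjusted p = 0.816 with an estimated correlation, and they had 0.589 and 0.612 with fry. The former had adjusted p of 0.301 and 0.0551 without psae1-3 replicate B and double mutant replicate B, and cytosolic ribosomal proteins had 0.209, with a median of 0.09 log2, without psae1-3 replicate A and 0.729 without double mutant replicate A. Antioxidants had a median of −0.08 log2, a mean of 0.42 log2 and a list test pointing down with adjusted p = 0.766.

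For some genes the change on losing STN7 differed between the wild-type and the psad1-1 background, and here the difference of the 2 effects was tested. AT4G14090 changed by −3.28 log2 in stn7-1 against Col-0 and by 0.38 log2 in the psad1-1 background, a difference of 3.66 log2 (SE 0.96, adjusted p = 0.0228), and UGT78D2 differed by 1.39 log2 (SE 0.22, adjusted p = 0.00249) and UF3GT by 3.17 log2 (SE 0.62, adjusted p = 0.00606). AT4G14090 did not pass without stn7-1 replicate A (adjusted p = 0.0518), psad1-1 replicate A (0.0529) or psad1-1 replicate B (0.0934), nor UF3GT without psad1-1 replicate B (0.0508). SWEET2 differed by −1.33 log2 (SE 0.17, adjusted p = 0.00117), PORB by −1.39 log2 (SE 0.24, adjusted p = 0.00311) and AT5G62720 by −1.98 log2 (SE 0.25, adjusted p = 0.00117). In all, 1610 probe sets passed, 791 higher and 819 lower. The count was 411 without psad1-1 replicate B and 955 without double mutant replicate B. Under scaling to the array median 24.9% were higher where the scaling used here gave 49.1%, with the median of all at −0.14 log2.

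Flavonoids and anthocyanins were higher in this difference (4 of 4 higher, median 3.27 log2, adjusted p = 0.000444). Tetrapyrrole synthesis (3 of 4 lower, median −0.61 log2, adjusted p = 0.00963), plastid ribosomal proteins (2 of 4 lower, median −0.49 log2, adjusted p = 0.0188) and antioxidants (2 of 5 lower, median −0.61 log2, adjusted p = 0.0328) were lower as lists. These 4 lists had adjusted p of 0.26, 0.26, 0.322 and 0.322 with an estimated correlation. AT4G14090, DFR and UF3GT had already fallen in psad1-1, to 24.6 and 24.2, 44.9 and 45.1, and 30.6 and 17.7 on its arrays. The stn7-1 arrays read 13.3 to 21.4, 20.4 to 48.7 and 18.3 to 25.4. All these psad1-1 signals lay above the background, so some further fall in the double mutant could have been seen. The double mutant arrays instead read 28.2 to 40.1, 50.15 to 102 and 31.0 to 38.7, each above every psad1-1 array. These 3 rises did not pass singly. UGT78D2 had not fallen in psad1-1 (300 and 319). A fall as large as in stn7-1 would have taken AT4G14090, DFR and UF3GT under the background. The size of the difference is therefore not fixed for them, and the flavonoid list result by itself is not read as a different effect of STN7. Without psad1-1 replicate A the plastid ribosomal proteins had adjusted p = 0.0848, and the antioxidants and oxidative stress markers had 0.0586 without Col-0 replicate A, 0.0794 without stn7-1 replicate B and 0.0650 without psad1-1 replicate B. Of the added lists, cytosolic ribosomal proteins (6 of 90 lower, median −0.39 log2, adjusted p = 1.15e-05) and the plastid-encoded lists for photosynthesis, the NDH complex and gene expression (0 of 33, 0 of 9 and 1 of 19 members past the test singly, adjusted p = 0.00589, 0.0324 and 0.00298) were lower as lists, each at adjusted p = 0.621 with an estimated correlation. With fry these 4 lists had adjusted p of 0.362, 0.366, 0.243 and 0.243. The plastid-encoded photosynthesis genes had adjusted p of 0.142 and 0.225 without Col-0 replicate B and psad1-1 replicate B. The plastid-encoded NDH complex had 0.117 and 0.304 without the same arrays, 0.0654 without stn7-1 replicate A and 0.0592 without double mutant replicate B. The list test pointed up for the glutathione S-transferases (1 of 7 higher, adjusted p = 0.0324, and 0.238 with an estimated correlation). Their adjusted p was 0.0987 without Col-0 replicate B and 0.0533 without stn7-1 replicate A, and they did not pass without psad1-1 replicate B. It also pointed up for the calmodulin-like proteins (1 of 5 higher, adjusted p = 0.0425, and 0.238 with an estimated correlation). That list did not pass without Col-0 replicate B or C, stn7-1 replicate A, psad1-1 replicate B or double mutant replicate A or B.

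Against the psae1-3 background, whose arrays belong to the other set, the difference of the STN7 effects passed for more probe sets. AT1G76960 differed by 11.82 log2, AT1G66100 by 8.77 log2, ECS1 by 8.06 log2 and CML41 by 4.69 log2. UGT78D2 differed by 1.18 log2 (SE 0.24, adjusted p = 0.00199) and AT4G14090 by 3.57 log2 (SE 1.01, adjusted p = 0.0181), the latter with adjusted p = 0.0995 without psae1-3 replicate B and 0.120 without double mutant replicate A. The signal of AT4G14090 was 8.75 ± 11.1 in psae1-3 and 7.44 ± 5.65 in psae1-3 stn7-1 (SD, n = 2 each), near the background, where a further fall could not be seen. UGT78D2 stood well above it, at 135 ± 29.3 and 197 ± 9.1. PORB differed by −1.68 log2 (SE 0.25, adjusted p = 0.000203), TAPX by −0.96 log2 and AT3G13120 by −1.26 log2. In all, 3121 probe sets passed, 1662 higher and 1459 lower, and the count was 1917 without double mutant replicate A. Under scaling to the array median 30.8% were higher where the scaling used here gave 53.3%, with the median of all at −0.16 log2.

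Plastid ribosomal proteins (4 of 4 lower, median −1.10 log2, adjusted p = 0.000205) and tetrapyrrole synthesis (2 of 4 lower, 4 adjusted over the list alone, median −0.57 log2, adjusted p = 0.00762) were lower as lists in this difference. The list of flavonoids and anthocyanins was higher (4 of 4, median 2.98 log2, adjusted p = 0.00939). In psae1-3 its members AT4G14090, DFR and UF3GT had fallen to 8.75, 14.2 and 13.7, so a further fall could hardly be seen, and the list result is not read as a different effect of STN7. Their adjusted p with an estimated correlation was 0.24, 0.24 and 0.362, and that of flavonoids and anthocyanins was 0.0621 without psae1-3 replicate B. Antioxidants (1 higher and 3 lower of 5) had a median of −0.72 log2, a mean of 0.109 log2 and a list test pointing down with adjusted p = 0.0883 (0.0239 with fry). Cytosolic ribosomal proteins (53 of 90 lower, median −0.89 log2, adjusted p = 7.62e-19), plastid-encoded gene expression machinery (7 of 19 lower, median −0.97 log2, adjusted p = 0.000272) and plastid-encoded photosynthesis genes (0 of 33 past the test singly, adjusted p = 0.00835) were lower as lists. They had adjusted p = 0.589, 0.589 and 0.643 with an estimated correlation and 0.056, 0.0881 and 0.370 with fry, and plastid-encoded photosynthesis genes 0.143 without Col-0 replicate B and 0.0796 without psae1-3 replicate B. Calmodulin-like proteins were higher (3 of 5, median 2.56 log2, adjusted p = 0.0111, and 0.165 with an estimated correlation).

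The 2 wild types, which also stand for the 2 array sets, differed strongly in single genes such as psaC, AT1G66100 and QQS (AT3G30720). The plastid gene psaC, which encodes an iron-sulfur subunit of photosystem I, was 1271 ± 57.5 in Wassilewskija (SD, n = 2) and 20.2 ± 6.08 in Col-0 (n = 3), a difference of 6.02 log2 (SE 0.26, adjusted p = 1.18e-10), and ndhD, a subunit of the NDH complex, was 3050 ± 357 and 127 ± 41.6 (4.64 log2). AT1G66100 differed by −9.01 log2 (adjusted p = 1.08e-14, at least 256-fold), AT3G22240 by −7.54 log2 (SE 0.16), the orphan starch gene QQS by −7.04 log2 (at least 25.4-fold), and STZ by −5.20 log2 (SE 0.45), from 1717 ± 808 in Col-0 to 48.2 ± 29.8. PORB was 1.27 log2 (SE 0.18, adjusted p = 3.26e-05) and GI 2.14 log2 (SE 0.45, adjusted p = 0.00114) higher in Wassilewskija, and the defensin gene PDF1.2 (AT5G44420) 2.59 log2 (adjusted p = 0.00303, and 0.0653 without Wassilewskija replicate A).

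Between Wassilewskija and Col-0, 6415 of 13648 probe sets passed, 3358 higher and 3057 lower (730 and 1319 at least 2-fold). Under scaling to the array median 69.4% of the calls were higher where the scaling used here gave 52.3%, with the median of all at 0.214 log2. No fixed list passed, although electron carriers (adjusted p = 0.0183), the Calvin cycle (0.0107) and tetrapyrrole synthesis (0.0287) passed as higher with fry, as did the dark-induced genes (0.000519). Light-harvesting complex II had a median of −0.02 log2 against a mean of 0.07 log2, and antioxidants (3 higher and 1 lower of 5) a median of 0.53 log2 against a mean of −0.69 log2. Plastid-encoded photosynthesis (28 of 33 higher, median 1.28 log2, adjusted p = 2.8e-09), NDH (8 of 9, median 2.86 log2, adjusted p = 1.92e-05) and gene expression (17 of 19, median 1.71 log2, adjusted p = 1.05e-07) were higher as plastid-encoded lists. They had adjusted p = 0.248, 0.237 and 0.237 with an estimated correlation. Calmodulin-like proteins (3 of 5 lower, median −3.05 log2, adjusted p = 0.00276), expansins (6 lower and 1 higher of 11, median −0.96 log2, adjusted p = 0.0301) and cytosolic ribosomal proteins (43 lower and 1 higher of 90, median −0.48 log2, adjusted p = 2.99e-07) were lower. They had adjusted p = 0.0897, 0.248 and 0.537 with an estimated correlation.

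The genes that differ between the wild types gave each mutant a position on a scale from Col-0 (0) to Wassilewskija (1). Each wild type also stands for its array set, so a position near 0 or 1 does not by itself show the accession. The wild-type arrays that fix the scale also chose the probe sets, so small distances from 0 or 1 are not interpreted. Over the 470 probe sets that passed between them with a difference of at least 2 log2, stn7-1 stood at 0.155 ± 0.051 (SD, n = 3), psad1-1 at 0.192 ± 0.037 (n = 2), psad1-1 stn7-1 at 0.160 ± 0.058 (n = 3), psae1-3 at 1.06 ± 0.003 (n = 2) and psae1-3 stn7-1 at 0.781 ± 0.041 (n = 2). Over the 2049 with a difference of at least 1 log2, psad1-1 stn7-1 stood at 0.063 ± 0.0398, stn7-1 at 0.111 ± 0.0119 and psad1-1 at 0.144 ± 0.0876. Along the chromosomes psae1-3 stayed between 0.988 and 1.04 in the chromosome medians, while psae1-3 stn7-1 stood at 0.568 on chromosome 1, 0.864 on chromosome 2, 0.855 on chromosome 3, 0.881 on chromosome 4 and 0.747 on chromosome 5. Probe sets changed at least 2-fold between the 2 psae1-3 lines made up 8.04% of those tested on chromosome 1 (153 of 1903), 2.46% on chromosome 2, 2.02% on chromosome 3, 2.53% on chromosome 4 and 4.90% on chromosome 5. The order of genes was read from their listed start positions, and these comparisons were chosen after the data were seen.

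**Figure D4:**
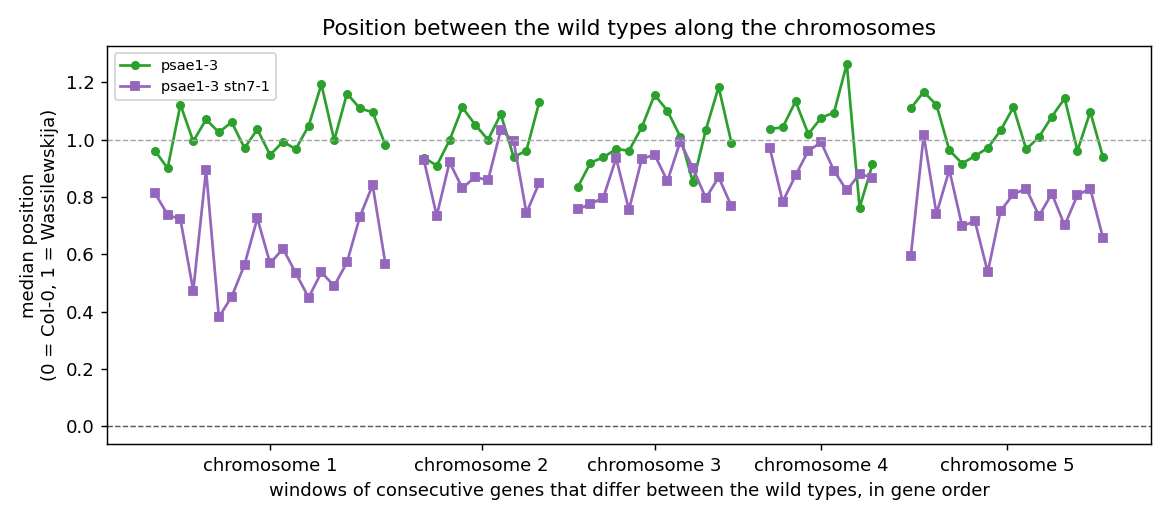
Median position of psae1-3 and psae1-3 stn7-1 on a scale from Col-0 (0) to Wassilewskija (1) in windows of at least 15 probe sets that differ between the wild types, in the order of the gene start positions along the 5 chromosomes (1039 probe sets in 67 windows). The chromosome medians of psae1-3 stn7-1 ran from 0.568 on chromosome 1 to 0.881 on chromosome 4, and those of psae1-3 from 0.988 to 1.04.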

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

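The tests that weigh explanations in this part were chosen after the results were seen. The differences between backgrounds, the scalings, the fits without 1 array and the counts of other splits of the arrays were planned.

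The difference between the stn7-1 effect in 2 backgrounds passed its test for 1610 probe sets (psad1-1) and 3121 probe sets (psae1-3). Of these, 962 (59.8%) and 1907 (61.1%) lie among the 54.2% of probe sets with an unadjusted p under 0.05 between the wild types, so this share does not set the psae1-3 background apart. Both differences contain the Col-0 arrays, which also enter the comparison of the wild types. For the double against the single mutants, which use no wild-type array, the shares were 56.8% (psad1-1) and 66.6% (psae1-3). The psae1-3 difference compares lines of both array sets and accessions, and these are not separated from STN7 in it. In the psad1-1 background the differences of single genes were 3.66 log2 for AT4G14090, 3.37 for DFR, 5.34 for AT3G01830, 3.35 for AT1G76960, 3.32 for AT3G14200, −1.98 for AT5G62720, −2.45 for AT1G23390, −2.59 for AT3G15570, −2.66 for AT2G20670 and −2.67 for AT5G26200. Several of these calls rest on single arrays. AT3G01830 had adjusted p of 0.0520 to 0.0910 without Col-0 replicate B or C, stn7-1 replicate A, psad1-1 replicate A or double mutant replicate B, and AT3G15570 had 0.0582 to 0.245 without Col-0 replicate B or C, any stn7-1 array or psad1-1 replicate B. AT4G14090 had 0.0518 to 0.0934 without stn7-1 replicate A or either psad1-1 array, and AT2G20670 had 0.0640 without psad1-1 replicate B. DFR had 0.0668 to 0.130 without Col-0 replicate B or C, stn7-1 replicate A or B, either psad1-1 array or double mutant replicate A or B. In the psae1-3 background they were 11.82 log2 for AT1G76960, 8.77 for AT1G66100, 8.06 for ECS1, 7.91 for CHI, 7.36 for AT1G35710, −2.65 for AT4G26370, −2.73 for AT5G62720, −2.74 for AT1G30250, −3.40 for AT1G20490 and −4.65 for AT5G15360. Some of these genes had every array of a genotype under the background of 8.15, so the sizes are not fixed. With such signals set to 8.15 the differences were 3.93 log2 for AT3G01830, 2.44 for AT1G76960, 1.33 for AT3G14200 and −1.70 for AT5G26200 in the psad1-1 background. In the psae1-3 background they were 9.45 for AT1G76960, 7.69 for AT1G66100, 5.86 for CHI and −3.32 for AT5G15360. A control probe set outside the comparisons read 1165 ± 309 (SD, n = 2) in psae1-3 and 865 ± 40.6 (n = 2) in psae1-3 stn7-1, against 4.47 (n = 2) in Wassilewskija, and was not analysed further.

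The first pattern weighed is that, of 322 single-gene probe sets that changed at least 2-fold between psae1-3 stn7-1 and psae1-3, 47.5% lay on chromosome 1, which held 26.2% of the 7266 tested. The percent of such probe sets had a range over the 5 chromosomes of 6.02 points here, 4.66 under quantile normalization and 5.62 under median scaling. At most a share of 3e-04 of 10000 random deals of blocks of 50 or 100 neighbouring probe sets gave as wide a range under any of these 3 scalings. The deals ask whether calls depend on the chromosome. They do not weigh scaling as a cause, since 1 factor per array acts on all chromosomes alike. Rotations of the whole gene order, which leave clusters intact and say nothing on scaling either, gave 0.446, and 0.0305 for chromosome 1 alone. RNA quality is argued against by the 3'/5' ratios of control genes, whose means differed by at most 0.150 log2 between the 2 lines. With any 1 of the 4 arrays left out the range was 4.93 to 5.83 points, which bears on single arrays and not on RNA quality. Loss of STN7 acting as in Col-0 plants is argued against for the 665 probe sets changed at least 2-fold. Of these 4.66% (31) passed the same way in stn7-1 and 24.8% (165) the opposite way, where 18.9% of all tested probe sets passed in stn7-1 in either direction. Probe sets that psae1-3 already shared with stn7-1 (427 higher and 301 lower in both) may have had less room to move again. Of 353 probe sets that changed at least 2-fold between the 2 lines and between the wild types, 94.6% (334) moved toward the Col-0 level. Among those with 1 known gene 97 of 97 did so on chromosome 1 and 78 of 81 elsewhere, although probe sets near the floor in both psae1-3 and Wassilewskija can only move that way. A candidate explanation consistent with these values is that psae1-3 stn7-1 carries chromosome segments of Col-0 origin, so that its differences from psae1-3 may reflect accession as well as STN7.

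The second pattern is the fall of flavonoid and anthocyanin transcripts in stn7-1 and psae1-3. RNA degradation is argued against by the 3'/5' ratios of control genes, whose largest mean shift was 0.311 log2, and although that of actin in psae1-3 replicate B was 0.598 above Wassilewskija, the flavonoids and anthocyanins passed without this array (median −2.15 log2, adjusted p = 0.00391). Scaling is argued against by the median change nearest to 0 under the 2 other scalings, which was −2.60 log2. A single array is argued against for the direction of the fall only. Each list member read lower on every stn7-1 array than on any Col-0 array, and likewise in psae1-3 against Wassilewskija. The highest adjusted p of the list without any 1 array was 0.00404, with a lone array assumed to vary like the other groups. That p cannot decide more, because it rests on the preset correlation of 0.01 between members. With an estimated correlation the list had adjusted p = 0.129 (stn7-1) and 0.150 (psae1-3) from all arrays. Against Wassilewskija, of the other array set, the list did not pass in stn7-1 (adjusted p = 0.267), so the planned rule did not call it there. Of its members UF3GT and UGT78D2 lost their psae1-3 call without Wassilewskija replicate B (adjusted p = 0.154 and 0.186) or psae1-3 replicate B (0.124 and 0.146). The growth light and any difference between plant batches stay open and were not tested, and the fall is a hypothesis about these genotypes until repeated.

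The third pattern is that more probe sets passed in psad1-1 (5521) than in stn7-1 (2580) against Col-0. Scaling is argued against by a ratio of counts of 2.00 at its lowest over the 2 other scalings. A single array as the whole cause is argued against, because the lowest psad1-1 count without 1 array (3868) was 1.44 times the highest stn7-1 count with or without 1 array (2685), with the lone psad1-1 array assumed to vary like the others. The bound on which this rests was set after the ratio of that lowest count to the stn7-1 count from all arrays, 1.499, had been seen, and the size of the difference stays open. Another time of harvest cannot be told apart, because the number of clock genes tested was 1 (GI, −3.74 log2 in psad1-1, at least 6.87-fold).

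The 10 ways of splitting the 6 arrays of a comparison are too few for a share under 0.05. For stn7-1 against Col-0 the real split gave 2580 probe sets and the highest other split 5, and for psad1-1 stn7-1 against Col-0 5572 and 1.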

How the results depend on the processing

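Keeping the deposited scales was the form first planned, and it was run as an alternative after the data were seen, when the common trimmed mean had replaced it. Using only the arrays of the same set was also chosen after the data were seen, and the other settings were planned. Of 591 values of named genes, 544 kept direction and side of the threshold under scaling to the array median, 27 no longer passed, 20 came to pass and 0 reversed. Under quantile normalization these counts were 550, 35, 4 and 2. The genes that reversed were PSBY (−0.0714 log2) and LHCB4.1 (−0.16 log2) in Wassilewskija against Col-0; the cause was not tested. Over 3568 values with 1 array left out 3064 kept direction and side, 467 no longer passed and 0 reversed. Of 180 list results 50 passed in the main setting, and with an estimated correlation all 50 no longer passed. The 130 that stayed as they were had not passed before. The list of cytosolic ribosomal proteins reversed between psae1-3 stn7-1 and psae1-3 without psae1-3 replicate A (median 0.0886 log2, where the fits without 1 array ran from −0.531 to 0.0886).

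With a minimum change of 2-fold the counts against both wild types were 115 (stn7-1), 1034 (psad1-1), 246 (psae1-3), 1009 (psad1-1 stn7-1) and 292 (psae1-3 stn7-1). Against the wild type of the same set they were 328, 1761, 366, 1591 and 763, for the double against the single mutants 87 (psad1-1) and 665 (psae1-3), for Wassilewskija against Col-0 2049, and for the interactions 615 and 1652. These are fewer by construction. Against Col-0 or Wassilewskija alone the counts were 2580 and 6884 for stn7-1, 5521 and 7248 for psad1-1, and 6575 and 2214 for psae1-3 stn7-1. The count was 7294 for psae1-3 against Col-0 and 8004 for psad1-1 stn7-1 against Wassilewskija, where the array set differs as well.

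Array weights gave 3952 for stn7-1 against Col-0. With the deposited scales kept, psae1-3 against both wild types gave 790 and Wassilewskija against Col-0 13270, since targets differ 5-fold, and single genes were not computed there. A fit of only the groups compared gave 672 for psae1-3 against both wild types, 931 against Wassilewskija and 31 for psad1-1 stn7-1 against psad1-1. That last count was 120 with only the arrays of the same set, 112 without a filter, 177 without the trend, 47 with a replicate block and 186 with array weights. Without the 7393 probe sets with an unadjusted p under 0.05 between the wild types (6255 tested) the counts were 117 and 440 for the double against the single mutants and 571 and 1125 for the interactions, fewer in part because fewer were tested. Of the 1677 calls between the psae1-3 lines 66.6% were among those left out, against 54.2% of all tested. The causes of the other changes were not tested.

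Leaving out 1 array gave counts of 1326 to 2685 for stn7-1 against Col-0 (728 to 1294 against both wild types), 3868 to 5098 for psad1-1 (2560 to 3173), 548 to 1245 for psae1-3 against Wassilewskija (414 to 1167), 4713 to 5124 for psad1-1 stn7-1 (3300 to 3480) and 1274 to 1547 for psae1-3 stn7-1 (659 to 1100). The double against the single mutants gave 19 to 366 (psad1-1) and 769 to 1335 (psae1-3), the interactions 411 to 1837 and 1917 to 3201, and Wassilewskija against Col-0 4646 to 6060. Signals under the background of 8.15 limit the folds of genes such as AT1G66100 and AT1G76960 to lower bounds.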

Other observations

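The comparisons in this part were chosen after the data were seen. Several genes moved the same way in psad1-1 against Col-0 and in psae1-3 against Wassilewskija, comparisons that share no array. The glutaredoxin-family gene AT3G62950 rose from signals near or under the background of 8.15 to 129 ± 13.1 (SD, n = 2, at least 12.7-fold) and 43.3 ± 20.8 (n = 2, at least 5.00-fold). UF3GT changed by −2.50 and −2.21 log2 (the latter at least 4.22-fold). Its psae1-3 call is lost without Wassilewskija replicate B or psae1-3 replicate B. In all, 421 probe sets were higher in both comparisons, where independent calls would give 143, and 416 lower in both, where they would give 199; 94 and 41 went opposite ways (182 and 156 for independent calls). Across probe sets, which are not independent replicates, the changes correlated at 0.340.

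For stn7-1 against Col-0 and psae1-3 against Wassilewskija, 427 probe sets were higher in both (72.0 for independent calls) and 301 lower in both (86.3), with 10 and 6 opposite (91.7 and 67.7) and a correlation across probe sets of 0.522. The double mutants against their wild types shared 372 higher (195) and 489 lower (259), but 154 and 206 went opposite ways (231 and 219 for independent calls), and the correlation was 0.121.

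The 25S rRNA control differed between genotypes of the first set, at 932 ± 361 (SD, n = 3) in Col-0, 1532 ± 141 (n = 3) in stn7-1, 1798 ± 467 (n = 2) in psad1-1 and 1551 ± 226 (n = 3) in psad1-1 stn7-1.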
